A study of Mus musculus with 16 samples.

How the data were processed

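Livers of 16 mice were measured, 1 mouse per array, on a one-colour Agilent SurePrint G3 mouse expression array with the Cy3 dye, per the labelling protocol; some sample labels give other dye names in a running series, and the arrays were treated alike. Per the file headers, each deposited array file held the intensity that Agilent Feature Extraction calls the processed signal, on a linear scale, with control probes removed and without any scaling between arrays. The processing notes name Feature Extraction 9.1, which subtracts the background and sets a floor. A table of all arrays was deposited as well and held the same values, with a largest difference of 0.005 after rounding. The files used here held no background, quality mark, position or slide column, so signal over background could not be computed and the slide of an array is not given in the sources used here. Median signals per array ran from 90.4 to 133 and 75th percentiles from 471 to 581. In 7 arrays between 2586 and 4377 probes shared a single lowest signal, and in the other 9 between 1 and 13 did. The first kind held 4 of 7 PHx glutamine arrays, 2 of 7 PHx placebo arrays and the sham glutamine array.

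The labels give the glutamine drink as 2% in the sample names and 0.6% in the protocol, and describe the drink for 7 days before and 6 days after surgery, while arrays reach day 7. The report therefore prints no dose. Groups and days were taken from the labels.

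Signals were taken to log2, and the 75th percentile of each array was subtracted. The design had named a filter on probes well above background; since that mark was not in the files, the fallback written with it was used, which kept probes above the 30th percentile of the array in at least 7 arrays. This left 33691 probes in the fit of all arrays. A gene was represented by its probe with the highest mean signal, and 8222 genes had more than 1 probe to choose from. Gene names came from the files, where 46359 probes carried 1 symbol and 10246 none, with 0 carrying several. Of 27309 gene numbers, 24828 were found in the RefSeq gene table of the mouse, used for names only, which renamed 2145 probes. Probes without a symbol entered no comparison of the report. Probe positions are printed as the files give them, in a genome build not given in the sources used here. Probes of families with near-identical members (Olfr, Vmn1r, Defa, Mup and Cyp genes) may bind more than 1 member, so those symbols are uncertain. In all, 21210 genes were tested in the fit of the 14 PHx arrays and 21379 in the fit of all 16, and 22 of them had a value at the lowest signal of an array.

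Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated tests), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The PHx arrays were fitted with the day as a factor and the drink, which sets each glutamine array against the placebo array of its day and leaves 6 residual degrees of freedom. This fit gave the glutamine term, the F-test over days and the linear slope over days 1 to 7. A drink by linear day term added to it left 5. All 16 arrays were fitted with 8 time points (sham and days 1 to 7) and the drink, with 7 residual degrees of freedom, for the mean of the 7 days against sham and for each day against sham. A drink by sham term added to it left 6, with the spread of the 1 sham pair taken to be that of the PHx pairs. Since each combination of surgery, drink and day had 1 mouse, the spread between mice treated alike was not measured. The error of each fit came from how the drink difference varied between its time points. It mixes the spread between mice with any effect of the drink that differs by day. The check of the pairing by day was the correlation, across genes, of the deviations of the 2 arrays of a day: it was 0.824, 0.145, 0.694, -0.227, 0.731, 0.613 and 0.393 on days 1 to 7, above 0.1 on 6 of 7 days.

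Gene lists of pathways and cell types, 40 in number with 947 members, were written out, of which 903 were measured in the PHx fit and 905 in the fit of all arrays; a gene may stand in more than 1 list. They were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, with camera on ranks and with fry, adjusted over the 40 lists. A list's mean was also compared between drinks with an exact two-sided sign-flip permutation test over the 128 sign patterns of the 7 daily differences. The design, lists, named genes, tests and first set of alternatives were chosen before the data were examined. Named genes are, for the 3 main comparisons, the 8 highest and 8 lowest changes past the threshold, with the same sign on all 7 days for glutamine and for PHx against sham. Where fewer than 10 genes passed, the 10 with the smallest unadjusted p are named. For each list up to 3 members with the smallest unadjusted p are named, for each day against sham the 2 highest and 2 lowest, and a fixed panel of liver and cell cycle genes may appear anywhere. Genes with only a clone or model name are counted and not named. The values of a few genes that this rule selects are not reported here.

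The fits were tested on simulated data of the same design with 200 changed genes, 100 at a log2 size of 1 and 100 at 2. For glutamine against placebo, with 21210 genes, 71% and 93% were called. For the slope (size over days 1 to 7) these were 43% and 90%, for PHx against sham, with 21379 genes, 44% and 87%, and for day 4 against sham 19% and 71%. The interaction with the day called 0% and 2%, and the term between the sham and PHx effects 0% and 10%, so these tests could miss large differences. With no changed gene there were 0 calls in each. A list, oxidative phosphorylation, shifted by -0.5 was called by camera (adjusted p = 1.4e-54), by the estimated correlation (adjusted p = 7.43e-05) and by fry (adjusted p = 1.89e-07), with a mean of -0.483. Fry also called 1 other list. In all these simulations genes varied independently, while the real members of this list had an estimated correlation of 0.495. The simulated calls thus do not show how the list tests behave with correlated genes.

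Alternatives covered quantile normalization, no filter and a stricter filter, the mean of a gene's probes, a trend and robust variance prior, array weights, a minimum change, the coding of days, the model terms, the list tests and leaving out each day and each sham array. The deposited table of all arrays was also run. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.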

Results

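RNA from 16 mouse livers was measured on 16 one-colour Agilent arrays, each with 1 signal per probe. The mice were male C57BL/6 and had either partial hepatectomy (PHx), the removal of 70% of the liver that sets off its regrowth, or sham surgery without resection. They drank glutamine or, as placebo, phosphate-buffered saline. The PHx placebo group and the PHx glutamine group held 7 arrays each, 1 per day from day 1 to day 7 after surgery. The sham placebo group and the sham glutamine group held 1 array each, both from day 4. Every array came from a different mouse, and no combination of surgery, drink and day was repeated. The mouse numbers in the sample names ran from 1 to 20 with glutamine and from 22 to 40 with placebo. The drink thus cannot be told apart from whatever these numbers reflect. The median signal of an array lay between 90.4 and 133, its 75th percentile between 471 and 581, and its highest signal between 590316 and 766077. The number of arrays limits the precision of every value.

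Spearman's rho between arrays, across probes that are not independent replicates, ran from 0.918 to 0.991 over the 120 pairs. On the first principal component, with 43.3% of the variance, the PHx glutamine array of day 4 lay at -117, far from the placebo array of its own day at 32.4. The arrays of day 3 lay at -61.2 with placebo and -71.4 with glutamine, and the sham arrays at 45.8 and 19.8. The second component, with 21.1% of the variance, held the day 1 arrays apart, at 90.9 with placebo and 87.9 with glutamine.

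**Figure D1:**
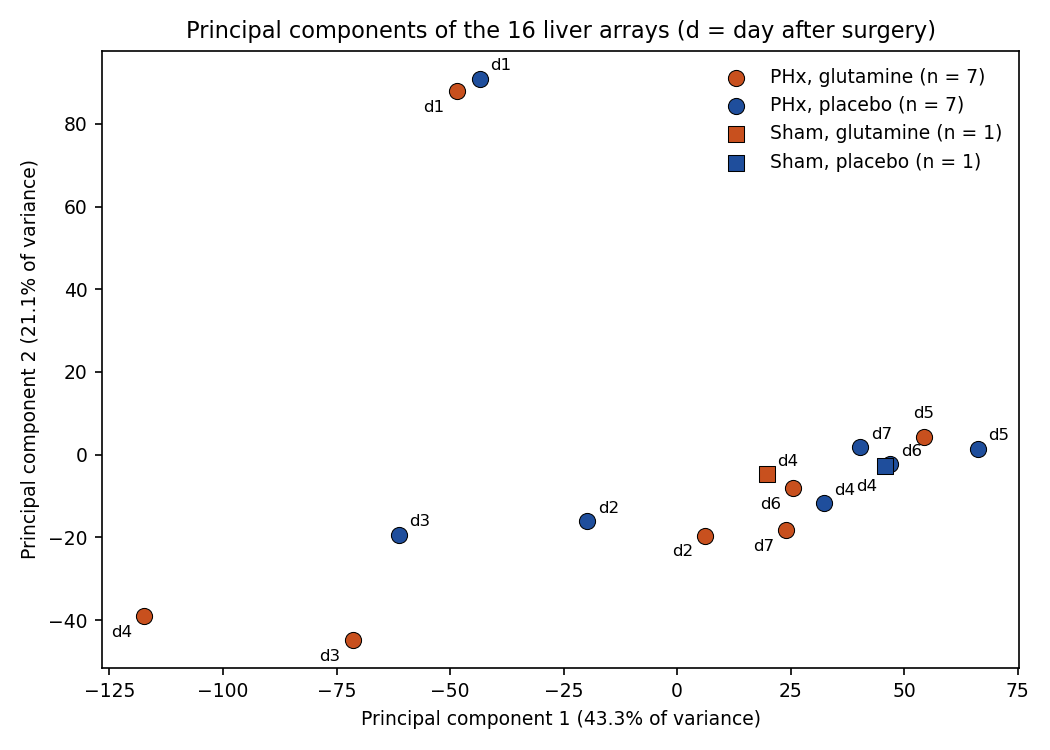
Each point is 1 of the 16 arrays, placed by its scores on the first principal component (43.3% of the variance) and the second (21.1%), with colour for the drink, shape for the surgery and a label for the day. The day 1 arrays sit at 90.9 and 87.9 on the second component, and the PHx glutamine array of day 4 sits at -117 on the first.

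The first question was how gene expression moved over the 7 days after PHx, with the drink as a term in the model. Immediate early genes, the transcription factors and stress regulators that cells switch on within hours of a stimulus, fell from day 1 to day 7: 19 of 21 measured members fell over all genes tested, and 19 adjusted over the list alone. Gadd45b, a stress-inducible growth regulator, fell by 0.85 log2 units per day (SE 0.0466, adjusted p = 0.000152), Fos by 0.88 (SE 0.115, adjusted p = 0.00305), Atf3 by 0.70 (SE 0.0535) and Nr4a1 by 0.42 (SE 0.0303). Cholesterol synthesis genes rose, with 16 of 23 members higher and 1 lower over all genes tested, or 18 and 3 adjusted over the list alone. Idi1 rose by 0.51 log2 units per day (SE 0.0605), Sqle, which makes the epoxide of squalene, by 0.53 (SE 0.0727), and Stard4, a cholesterol carrier, by 0.28 (SE 0.0356). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (gene number 13122, probe on chromosome 4 at 6193456 to 6193515), had the steepest rise of any named gene, 1.06 log2 units per day (SE 0.177, adjusted p = 0.00618).

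Other genes with steep rises were the cell division genes Cdkn3 (1.01 log2 units per day, SE 0.287), Psrc1 (0.88, SE 0.180), Pimreg (0.72, SE 0.165) and Cdc20 (0.68, SE 0.176). Ccr2, the chemokine receptor of inflammatory monocytes, rose by 0.69 (SE 0.0878), the interferon-inducible Gbp11 by 0.64 (SE 0.125) and Kctd21 by 0.77 (SE 0.180). Cidec, a lipid droplet protein, had a slope of -1.17 (SE 0.248), Hilpda, a lipid droplet protein induced by low oxygen, -0.94 (SE 0.111), and Pdk4, which restrains pyruvate oxidation, -0.90 (SE 0.223). Ppp1r3g, a glycogen-targeting subunit of a phosphatase, fell by 0.97 (SE 0.174), the lipid transporter Mfsd2a by 0.95 (SE 0.145), Rab30 by 0.92 (SE 0.131) and Igfbp1, a secreted binder of insulin-like growth factors, by 0.87 (SE 0.183). Among the Wnt targets that mark the cells around the central vein, Axin2 rose by 0.47 (SE 0.0912; 1 of its 2 probes in this direction) and Lgr5 by 0.42 (SE 0.0808). The collagen Col3a1 rose by 0.27 (SE 0.0756), and Cdkn1a, an inhibitor of the cell cycle, fell by 0.83 (SE 0.143).

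Of the 40 gene lists, 10 moved as groups along the days in the camera test, 5 up and 5 down. Immediate early genes had a median slope of -0.43 log2 units per day (adjusted p = 8.06e-12; adjusted p = 0.495 with an estimated correlation). Cholesterol synthesis had a median of 0.26 and G2/M genes, which act in mitosis, a median of 0.34, each with adjusted p = 1.63e-07. Both calls were lost with an estimated correlation (adjusted p = 0.942 with an estimated correlation for each). In the G2/M list 4 of 36 members rose over all genes tested and 0 adjusted over the list alone. Markers of macrophages and Kupffer cells, the resident macrophages of the liver, rose (median 0.17, adjusted p = 2.23e-05; adjusted p = 0.942 with an estimated correlation), with 10 of 21 members higher and 1 lower, or 13 and 1 adjusted over the list alone. Ccr2, Mpeg1 (0.22, SE 0.0428) and Fcgr1 (0.26, SE 0.0523) were among them. Interferon response genes, the antiviral program, rose (median 0.20, adjusted p = 0.000205; adjusted p = 0.942 with an estimated correlation), with 6 of 25 members higher, or 9 adjusted over the list alone, among them Oas2 (0.26, SE 0.0448) and Irf9 (0.37, SE 0.0857). Lymphocyte markers rose (median 0.07, adjusted p = 0.0132; adjusted p = 0.495 with an estimated correlation), with 7 of 19 members higher and 1 lower on either adjustment, among them the T cell genes Thy1 (0.30, SE 0.0429) and Cd2 (0.30, SE 0.0431).

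The other falling lists were small in size. Fatty acid oxidation and PPARa target genes had a median slope of -0.13 (adjusted p = 9.24e-05; adjusted p = 0.942 with an estimated correlation), with 1 of 30 members higher and 11 lower, or 1 and 19 adjusted over the list alone. Cyp4a10 (-0.35, SE 0.0672), Cyp4a31 (-0.33, SE 0.0576) and Ech1 (-0.18, SE 0.0304) fell. Ribosome biogenesis genes had a median of -0.09 (adjusted p = 0.000198; adjusted p = 0.942 with an estimated correlation), with 10 of 28 members lower, or 11 adjusted over the list alone, among them the nucleolar genes Nop58 (-0.32, SE 0.0383) and Nolc1 (-0.19, SE 0.0312). Oxidative phosphorylation genes had a median of -0.07 (adjusted p = 3.93e-05; adjusted p = 0.942 with an estimated correlation) and a mean of -0.07, which quantile normalization turned to 0.0057, with 7 of 31 members lower, or 11 adjusted over the list alone. Skeletal and smooth muscle genes had a median of -0.08 (adjusted p = 0.0440; adjusted p = 0.942 with an estimated correlation), with 2 of 13 members lower, or 4 adjusted over the list alone. The camera adjusted p of the other 30 lists ran from 0.0616 to 0.970.

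With limma, 3827 of 21210 genes had a slope at an adjusted p under 0.05, 2023 up and 1804 down, and 7944 at an unadjusted p under 0.05. The F-test over the 7 days, which asks for any difference between days, passed 3048 genes, and 1846 passed both. Both tests rested on day 1: without it 3 genes passed for the slope (1 up and 2 down), 0 passed the F-test, and all 16 genes with the steepest slopes missed the threshold (adjusted p from 0.0739 for Ccr2 to 0.428 for Kctd21), with slopes of -0.57 for Fos, -0.42 for Hilpda, 0.31 for Kctd21 and -0.57 for Ppp1r3g. Counts for the slope were 7419 without day 4, 1890 without day 5 and 1577 without day 6, and for the F-test 1710 without day 3, 8959 without day 4, 1166 without day 5 and 1714 without day 6. Cdkn3 had slopes of 0.42, 0.50 and 0.61 without days 5, 6 and 7 and 0.46 with quantile normalization, and Cdc20 had 0.30, 0.39 and 0.44 without days 5, 6 and 7. Mean list slopes without day 1 were -0.22 against -0.45 for immediate early genes, 0.08 against 0.21 for cholesterol synthesis and 0.41 against 0.18 for the interferon response. The interferon mean was 0.12 without day 3, and the macrophage mean was 0.08 without day 6 against 0.15. Muscle genes missed the threshold without day 1, 3 or 5 (adjusted p 0.0510, 0.0570 and 0.115) and lymphocyte markers without day 2, 4, 6 or 7 (0.0683, 0.0567, 0.0958 and 0.0982).

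**Figure D2:**
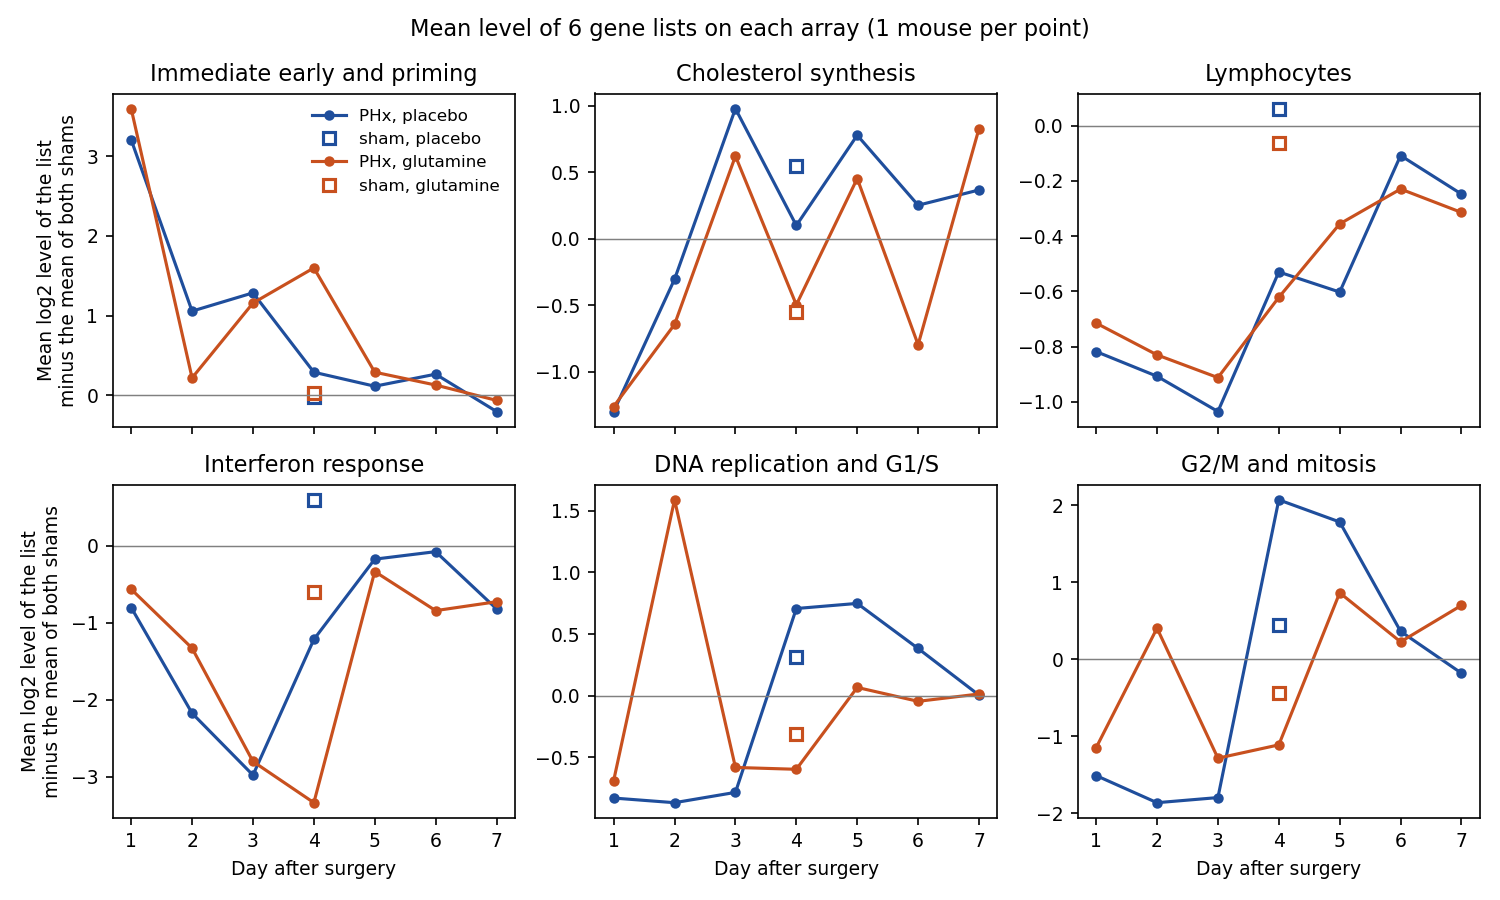
Each panel plots, for 1 gene list, the mean log2 signal of its members minus that of the 2 sham arrays (vertical axis) against the day after PHx (horizontal axis), with 1 line per drink and 1 array per point. Immediate early genes lie at 3.20 with placebo and 3.60 with glutamine on day 1 and at -0.20 and -0.06 on day 7, and the G2/M list lies at 2.07 with placebo and -1.11 with glutamine on day 4.

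The second question was how the liver after PHx differed from the sham liver. Both sham arrays came from day 4. Apart from day 4, a difference from sham therefore cannot be split between the resection and the time since surgery. Averaged over the 7 days, 1 gene passed: Lamb3, a chain of the basement membrane protein laminin (gene number 16780, probe on chromosome 1 at 195170009 to 195170068), was 3.94-fold higher after PHx (log2 1.98, SE 0.193, adjusted p = 0.0189) and higher on 7 of 7 days. Its level, in log2 units relative to the array's 75th percentile, was 1.32 with placebo and 1.19 with glutamine on day 1 and -1.76 and -1.55 on day 7, against -2.37 and -2.53 in the sham arrays. Interferon response genes were lower after PHx as a group (median -1.39, adjusted p = 2.36e-15; adjusted p = 0.375 with an estimated correlation), and so were markers of macrophages and Kupffer cells (median -0.87, adjusted p = 1.39e-11; adjusted p = 0.287 with an estimated correlation). Lymphocyte markers were lower (median -0.42, adjusted p = 1.82e-07), and theirs was the 1 call that held with an estimated correlation (adjusted p = 0.0360 with an estimated correlation). Immediate early genes were higher (median 0.94, adjusted p = 4.43e-10; adjusted p = 0.287 with an estimated correlation).

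No member of a list passed over all 21379 genes in this average, so the members are given as values. In the interferon list 17 of 25 members were lower adjusted over the list alone, with Cxcl9, a chemokine induced by interferon gamma, at -2.31 (SE 0.369) and Gbp2 at -1.40 (SE 0.254). Among macrophage markers 11 of 21 were lower adjusted over the list alone, with the Kupffer cell receptor Timd4 at -0.91 (SE 0.190), Csf1r at -0.75 (SE 0.159) and Ccr2 at -2.22 (SE 0.489). Among lymphocyte markers 9 of 20 were lower adjusted over the list alone, with the cytotoxic granule genes Gzmb at -1.09 (SE 0.167) and Nkg7 at -1.61 (SE 0.251) and the T cell receptor chain Cd3g at -2.10 (SE 0.383). Of the immediate early genes 8 of 21 were higher adjusted over the list alone, with Myc at 1.73 (SE 0.324) and Gadd45b at 1.26 (SE 0.262).

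Lists of metabolism and protein synthesis also differed from sham. Fatty acid oxidation and PPARa target genes were higher (median 0.51, adjusted p = 2.51e-07; adjusted p = 0.398 with an estimated correlation), with Acot2 at 1.37 (SE 0.339) and 0 of 30 members passing adjusted over the list alone. Oxidative phosphorylation genes were higher (median 0.19, adjusted p = 2.07e-06; adjusted p = 0.628 with an estimated correlation), with 0 of 31 members passing adjusted over the list alone; with quantile normalization their mean was 0.04 and the call was lost (adjusted p = 0.446). Amino acid response and endoplasmic reticulum stress genes were higher (median 0.43, adjusted p = 2.00e-05; adjusted p = 0.287 with an estimated correlation), with the chaperone Hspa5 at 1.25 (SE 0.297) and 1 of 28 members higher adjusted over the list alone. Ribosome biogenesis genes were higher (median 0.27, adjusted p = 8.12e-05; adjusted p = 0.628 with an estimated correlation), with Rrp12 at 1.04 (SE 0.231) and 3 of 28 members higher adjusted over the list alone. Basement membrane genes were higher (median 0.10, mean 0.31, adjusted p = 0.0147; adjusted p = 0.287 with an estimated correlation), a call that was also lost on ranks (adjusted p = 0.107), with the type IV collagen chains Col4a1 at 1.32 (SE 0.283) and Col4a2 at 1.08 (SE 0.187) and 4 of 14 members higher adjusted over the list alone. Lipogenesis genes, which make fatty acids, were lower (median -0.41, adjusted p = 0.00494; adjusted p = 0.628 with an estimated correlation), with Scd1 at -1.99 (SE 0.608) and 0 of 21 members passing adjusted over the list alone. The camera adjusted p of the other 30 lists ran from 0.0648 to 0.979.

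With limma, 2386 of 21379 genes had an unadjusted p under 0.05, 1155 higher and 1231 lower. The genes with the next smallest p did not pass: the natural killer receptor Klra2 (log2 -1.44, adjusted p = 0.0543), Ncmap (-2.23, adjusted p = 0.0543), the alkaline phosphatase Alpl (1.91, adjusted p = 0.0547), Sun3 (-1.45, adjusted p = 0.105) and, at an adjusted p of 0.119 each, Gzmb, Nkg7, Denn2b (2.05), Myo1f (-1.41) and Clec4b1 (-1.43). Lamb3 missed the threshold without day 1 (adjusted p = 0.150), day 2 (0.125), the sham placebo array (0.180) or the sham glutamine array (0.666), and with the mean of a gene's probes (0.112), where Ncmap passed (0.0444). The count of genes was 0 without day 1, day 2 or the sham glutamine array, 5 without day 6, day 7 or the sham placebo array, 396 without day 4 and 217 without the PHx glutamine array of day 4 alone. Without the sham glutamine array 19 lists passed in place of 10, ribosome biogenesis missed (mean 0.11 against 0.30, adjusted p = 0.217) and the amino acid response mean was 0.24 against 0.46. Without the sham placebo array lipogenesis missed (mean -0.20 against -0.39, adjusted p = 0.226), the interferon mean was -0.82 against -1.30 and the ribosome mean 0.50. Lipogenesis also missed without day 3 (adjusted p = 0.0732) and basement membrane without day 5 (0.0555), and the immediate early mean was 0.51 against 0.92 without day 1.

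Set against the 2 sham arrays, both from day 4, day 1 after PHx differed in 3708 genes, 1475 higher and 2233 lower. Hilpda rose by 7.27 log2 units, 155-fold (SE 0.795, adjusted p = 0.000483), and Cdkn1a by 7.21 (SE 1.02, adjusted p = 0.00147; 2 of its 3 probes in this direction). Cyp7a1 fell by 6.76 (SE 1.26, adjusted p = 0.00563) and Kctd21 by 6.16 (SE 1.29, adjusted p = 0.00949). Immediate early genes were high: 16 of 21 members rose, or 19 adjusted over the list alone, with Atf3 at 6.15 (SE 0.379), Gadd45b at 6.02 (SE 0.346) and Nr4a1 at 3.49 (SE 0.214). In cholesterol synthesis 14 of 23 members fell and 3 rose, or 17 and 4 adjusted over the list alone. Sqle lay at -4.53 (SE 0.625), Idi1 at -4.17 (SE 0.476) and Stard4 at -2.14 (SE 0.252). Oxidative phosphorylation genes rose in 11 of 31 cases, or 16 adjusted over the list alone, and ribosome biogenesis genes in 9 of 28 on either adjustment, with Nop58 at 2.22 (SE 0.351).

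Also on day 1, 9 of 20 lymphocyte markers fell and 1 rose, or 11 and 2 adjusted over the list alone, with Cd3g at -2.74 (SE 0.506) and Nkg7 at -2.10 (SE 0.332). Of 21 macrophage markers 5 fell, with Ccr2 at -4.75 (SE 0.647) and the scavenger receptor Marco at -2.82 (SE 0.459); adjusted over the list alone 11 fell and 1 rose. In the list of p53 targets and growth arrest genes 6 of 24 rose and 3 fell on either adjustment, with the stress hormone Gdf15 at 5.83 (SE 0.471) and the cell cycle inhibitor Cdkn1b at -1.62 (SE 0.221). Of 14 Wnt targets 3 fell and 2 rose, or 5 and 3 adjusted over the list alone. Axin2 lay at -3.83 (SE 0.650, 1 of its 2 probes in this direction) and Lgr5 at -3.23 (SE 0.582). The smooth muscle actin Acta2 rose by 1.35 (SE 0.322). The day 1 count was 1397 without the sham placebo array, 1254 without the sham glutamine array and 5796 without day 4. Without either sham array Hilpda, Cdkn1a and Cyp7a1 passed and Kctd21 did not (adjusted p 0.0521 and 0.0775).

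**Figure D3:**
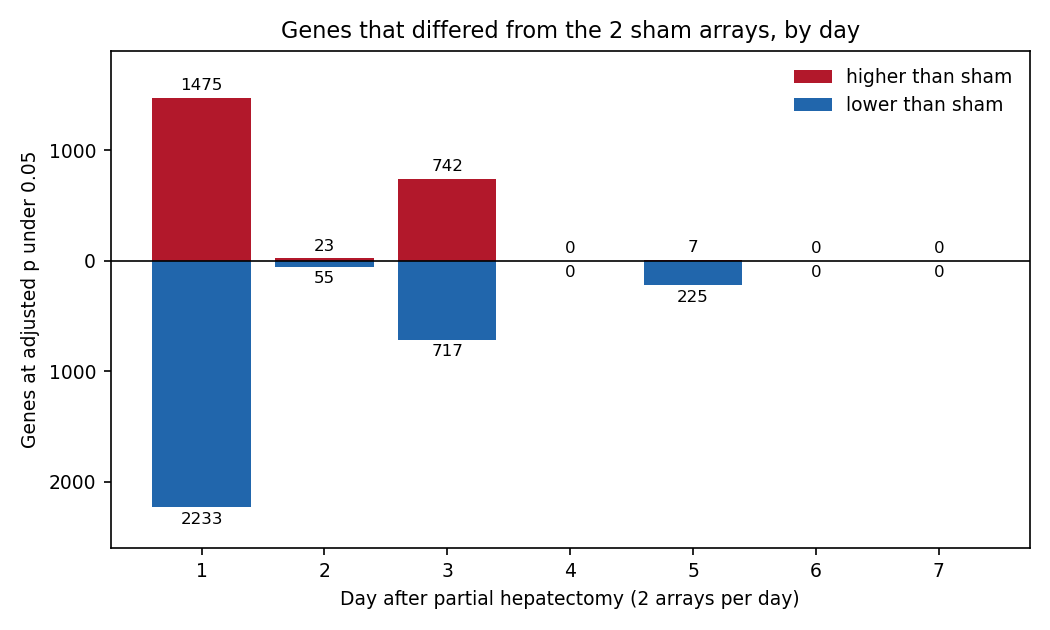
Bars give the number of genes at an adjusted p under 0.05 for each day after PHx against the 2 sham arrays (vertical axis, number of genes; horizontal axis, day), with genes higher than sham above 0 and genes lower below it. Day 1 has 1475 higher and 2233 lower genes, day 3 has 742 and 717, and days 4, 6 and 7 have 0.

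On day 2, 78 genes differed from sham, 23 higher and 55 lower. Apoa4, a lipoprotein component, rose by 4.73 log2 units (SE 0.823, adjusted p = 0.0448) and Chrdl2 by 3.95 (SE 0.485, adjusted p = 0.0204). Hamp2, of the hepcidin family of iron hormones, fell by 5.87 (SE 0.960, adjusted p = 0.0415), Cxcl9 by 4.18 (SE 0.488, adjusted p = 0.0198) and Nkg7 by 2.19 (SE 0.332). The list of lymphocyte markers had 3 of 20 members lower over all genes tested and 10 adjusted over the list alone, and that of fatty acid oxidation genes 0 of 30 over all genes tested and 20 higher adjusted over the list alone. Without the sham placebo array the day 2 count was 3, without the sham glutamine array 0, without day 1 15, without day 4 1054, without day 5 8 and without day 6 1. None of the 4 named genes of day 2 passed without either sham array.

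On day 3, 1459 genes differed from sham, 742 higher and 717 lower. Interferon response genes fell in 18 of 25 cases, or 24 adjusted over the list alone (median -2.79), with Cxcl10 at -4.65 (SE 0.705), Ifit3 at -4.59 (SE 0.751) and Cxcl9 at -4.33 (SE 0.488). Macrophage markers fell in 10 of 21 cases, with Cd5l at -2.37 (SE 0.420) and Timd4 at -1.49 (SE 0.252); adjusted over the list alone 17 fell and 2 rose. Lymphocyte markers fell in 9 of 20 cases on either adjustment, with Cd3g at -4.44 (SE 0.506). Of 21 lipogenesis genes 6 fell, or 11 with 1 higher adjusted over the list alone, with Scd1 at -4.40 (SE 0.805) and its regulator Srebf1 at -2.31 (SE 0.498). Sult1e1, which inactivates oestrogens, rose by 7.37 (SE 1.79, adjusted p = 0.0404) and Tg by 6.50 (SE 1.51, adjusted p = 0.0368). Hsd3b5, a male-biased steroid enzyme, fell by 9.84 (SE 2.53, adjusted p = 0.0460) and the carbonic anhydrase Car3 by 8.34 (SE 1.69, adjusted p = 0.0282). Hgf, the hepatocyte growth factor, rose by 1.67 (SE 0.412), while the macrophage marker Adgre1 (-2.07, SE 0.462), Col3a1 (-2.49, SE 0.540), Cyp7a1 (-5.40, SE 1.26) and the clock output gene Dbp (-3.17, SE 0.721) fell. The day 3 count was 2 without the sham placebo array, 0 without the sham glutamine array, 693 without day 1, 4432 without day 4, 554 without day 5 and 379 without day 6, and none of the 4 genes with the largest changes passed without either sham array.

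On day 5, 232 genes differed from sham, 7 higher and 225 lower. Loxl4, a matrix crosslinking enzyme, rose by 2.61 (SE 0.360, adjusted p = 0.0305) and Tuba8 by 2.06 (SE 0.384, adjusted p = 0.0402). The clock repressors Ciart and Per3 fell by 4.99 (SE 0.870, adjusted p = 0.0360) and 1.95 (SE 0.313, adjusted p = 0.0359), and Plppr1 fell by 3.26 (SE 0.609, adjusted p = 0.0402). Of 20 clock genes 2 fell, and adjusted over the list alone 8 fell and 2 rose. With quantile normalization 0 genes passed on day 5, and without day 2, day 6 or the sham glutamine array also 0; the count was 57 without day 3, 519 without day 4, 129 without day 7 and 4 without the sham placebo array. Without day 6 the brightest probe of Ciart was another one, at -1.01.

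On day 4, the day of the sham arrays, 0 genes passed in limma, with 4009 at an unadjusted p under 0.05 and 0.0810 as the smallest adjusted p. Adjusted over the list alone, 23 of 25 interferon response genes were lower (median -2.49), 13 of 21 macrophage markers (median -1.11), 8 of 20 lymphocyte markers and 8 of 23 genes of bile acid synthesis and transport, where 1 was higher. The day 4 glutamine array stood further from sham than the placebo array in the bile acid mean (-1.77 against -0.25) and the interferon mean (-3.34 against -1.22). Days 6 and 7 also had 0 genes, with 210 and 473 at an unadjusted p under 0.05. Without the sham placebo array the counts were 2, 1 and 2 on days 4, 6 and 7, and without day 3 the day 4 count was 1. All 7 comparisons share the 2 sham arrays, so their results are not independent.

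The third question was what glutamine changed in the regenerating liver, with each glutamine array set against the placebo array of its own day. By camera with its preset correlation 16 lists, most of them of liver metabolism, were lower with glutamine, but 33 of the 64 ways to assign the drink labels within days called as many lists. Genes of oxidative phosphorylation, the respiratory chain of mitochondria, had a median of -0.21 (adjusted p = 1.67e-10; adjusted p = 0.448 with an estimated correlation), and 31 of 31 fitted values lay below 0, among them Atp5b at -0.31 and Cox6c at -0.33. Cytochrome P450 and xenobiotic metabolism genes had a median of -0.59 (adjusted p = 6.37e-06; adjusted p = 0.518 with an estimated correlation), with 31 of 33 fitted values below 0, among them Cyp2a5 at -1.28. Bile acid synthesis and transport genes had a median of -0.37 (adjusted p = 3.43e-05; adjusted p = 0.448 with an estimated correlation), with Cyp7a1 at -1.58 and its regulator Nr1h4, the bile acid receptor, at -0.67. No member of these 3 lists passed the threshold, with 0 over all genes tested and 0 adjusted over the list alone.

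Fatty acid oxidation and PPARa target genes had a median of -0.20 (adjusted p = 7.36e-06; adjusted p = 0.448 with an estimated correlation), with Acadm at -0.52. Cholesterol synthesis had -0.33 (adjusted p = 8.14e-06; adjusted p = 0.461 with an estimated correlation), with Dhcr7 at -0.64. Lipogenesis had -0.38 (adjusted p = 4.25e-05; adjusted p = 0.448 with an estimated correlation), where 2 of 21 members were lower adjusted over the list alone. These included Me1, malic enzyme, at -0.70 (SE 0.113). Male-biased and growth hormone dependent genes had -0.47 (adjusted p = 8.46e-05), hepatocyte secreted proteins and transcription factors -0.14 (adjusted p = 0.000555) and periportal genes -0.38 (adjusted p = 0.00189), each with an adjusted p = 0.448 with an estimated correlation. Pericentral genes had -0.32 (adjusted p = 0.00121; adjusted p = 0.518 with an estimated correlation) and NRF2 oxidative stress genes -0.44 (adjusted p = 0.00262; adjusted p = 0.692 with an estimated correlation), where 1 of 23 was lower adjusted over the list alone and Hmox1 had a value of 0.70. Clock genes had -0.28 (adjusted p = 0.00899), gluconeogenesis and glycolysis -0.14 (adjusted p = 0.0107) and urea cycle genes -0.38 (adjusted p = 0.0107), with Ass1 at -0.65, each with an adjusted p = 0.448 with an estimated correlation. The interferon response had -0.25 (adjusted p = 0.0274; adjusted p = 0.782 with an estimated correlation). Glutamine and glutamate metabolism had -0.21 (adjusted p = 0.0494; adjusted p = 0.448 with an estimated correlation), with 20 of 30 fitted values below 0, the glutamine carrier Slc38a3 at -0.36, and Gfpt2, which uses glutamine to make hexosamines, at 0.64. The camera adjusted p of the other 24 lists ran from 0.0960 to 0.959. Among these, neutrophil (0.43, adjusted p = 0.201), acute phase (0.22, adjusted p = 0.148) and macrophage markers (0.20, adjusted p = 0.0960) and amino acid response genes (0.16, adjusted p = 0.487) had positive medians.

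The day 4 pair and the brightness of the probes moved with these lists. Without the PHx glutamine array of day 4 the mean of the P450 list was -0.12 against -0.61, that of pericentral genes -0.09 against -0.37 (adjusted p = 0.0708), of NRF2 genes -0.03 against -0.35 (adjusted p = 0.0924), of the interferon response 0.07 against -0.24 (adjusted p = 0.711), and of glutamine metabolism -0.07 against -0.13 (adjusted p = 0.0527). Without it the means of the urea cycle (-0.17 against -0.32), periportal (-0.18 against -0.32), bile acid (-0.25 against -0.42) and lipogenesis (-0.21 against -0.38) lists were also nearer 0. Over all genes tested, the dimmest 10% had a median difference of 0.26 with glutamine and the brightest 10% one of -0.15. With quantile normalization the calls of glutamine metabolism (adjusted p = 0.202), urea cycle (0.0692), periportal (0.0692), gluconeogenesis (0.332) and hepatocyte secreted protein genes (0.122) were lost, and 3 lists were higher and 11 lower in place of 0 and 16. The 3 were macrophage markers (mean 0.30, adjusted p = 0.00230), the acute phase (0.42, adjusted p = 0.000791) and the amino acid response (0.19, adjusted p = 0.0291). The mean of oxidative phosphorylation was then -0.10 against -0.22, that of fatty acid oxidation -0.14 against -0.24, and that of cholesterol synthesis -0.20 against -0.31. Among other left-out days, fatty acid oxidation had -0.10 without day 3, cholesterol synthesis -0.19 without day 6 and male-biased genes -0.26 against -0.40 without day 7. Clock genes missed without day 1 (adjusted p = 0.0542) or day 3 (-0.17, adjusted p = 0.0716), gluconeogenesis without day 3 (adjusted p = 0.0760), the interferon response without day 6 (-0.16, adjusted p = 0.192; without day 2 it had -0.42), and glutamine metabolism without day 1, 3, 5 or 6 (adjusted p 0.0598, 0.0699, 0.0601 and 0.0618).

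With limma 0 of 21210 genes passed for glutamine, with 3577 at an unadjusted p under 0.05, 2872 higher and 705 lower, and 0.238 as the smallest adjusted p. The unadjusted count was 2313 without day 3, 1996 with quantile normalization (1414 higher and 582 lower) and 1308 without the day as a block. The count past the adjusted p stayed at 0 in each. The 10 genes with the smallest p had this adjusted p. They had the same sign on 7 of 7 days, which choosing by p in a paired fit favours, so it adds no support. Among them were Me1 (-0.70, SE 0.113) and, with positive values, Csta3 (0.95), Lct (0.86), Olfr203 (0.73), Vmn1r148 (0.72), Olfr205 (0.68), Pianp (0.65), Shh (0.64) and Cyp11a1 (0.63). The proliferation marker Mki67 had a difference of 0.18 (SE 0.858) and Top2a one of 0.24 (SE 0.817). The glutamine synthetase gene Glul had -0.47 (SE 0.275) and the liver glutaminase Gls2 -0.57 (SE 0.253), both short of the threshold. In the exact two-sided sign-flip test of the 7 daily differences, the oxidative phosphorylation mean was -0.22 (SD 0.188). It was lower on 7 of 7 days, though on day 1 only at -0.003. The gluconeogenesis and glycolysis mean was -0.20 (SD 0.225) and lower on 7 of 7 days. Both lists had an exact p of 0.0156 in this test, the smallest that 7 pairs allow. After adjustment over the 40 lists each had 0.312, and 0 lists passed; clock and bile acid genes had an exact p of 0.0312 each and glutamine metabolism 0.0469.

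**Figure D4:**
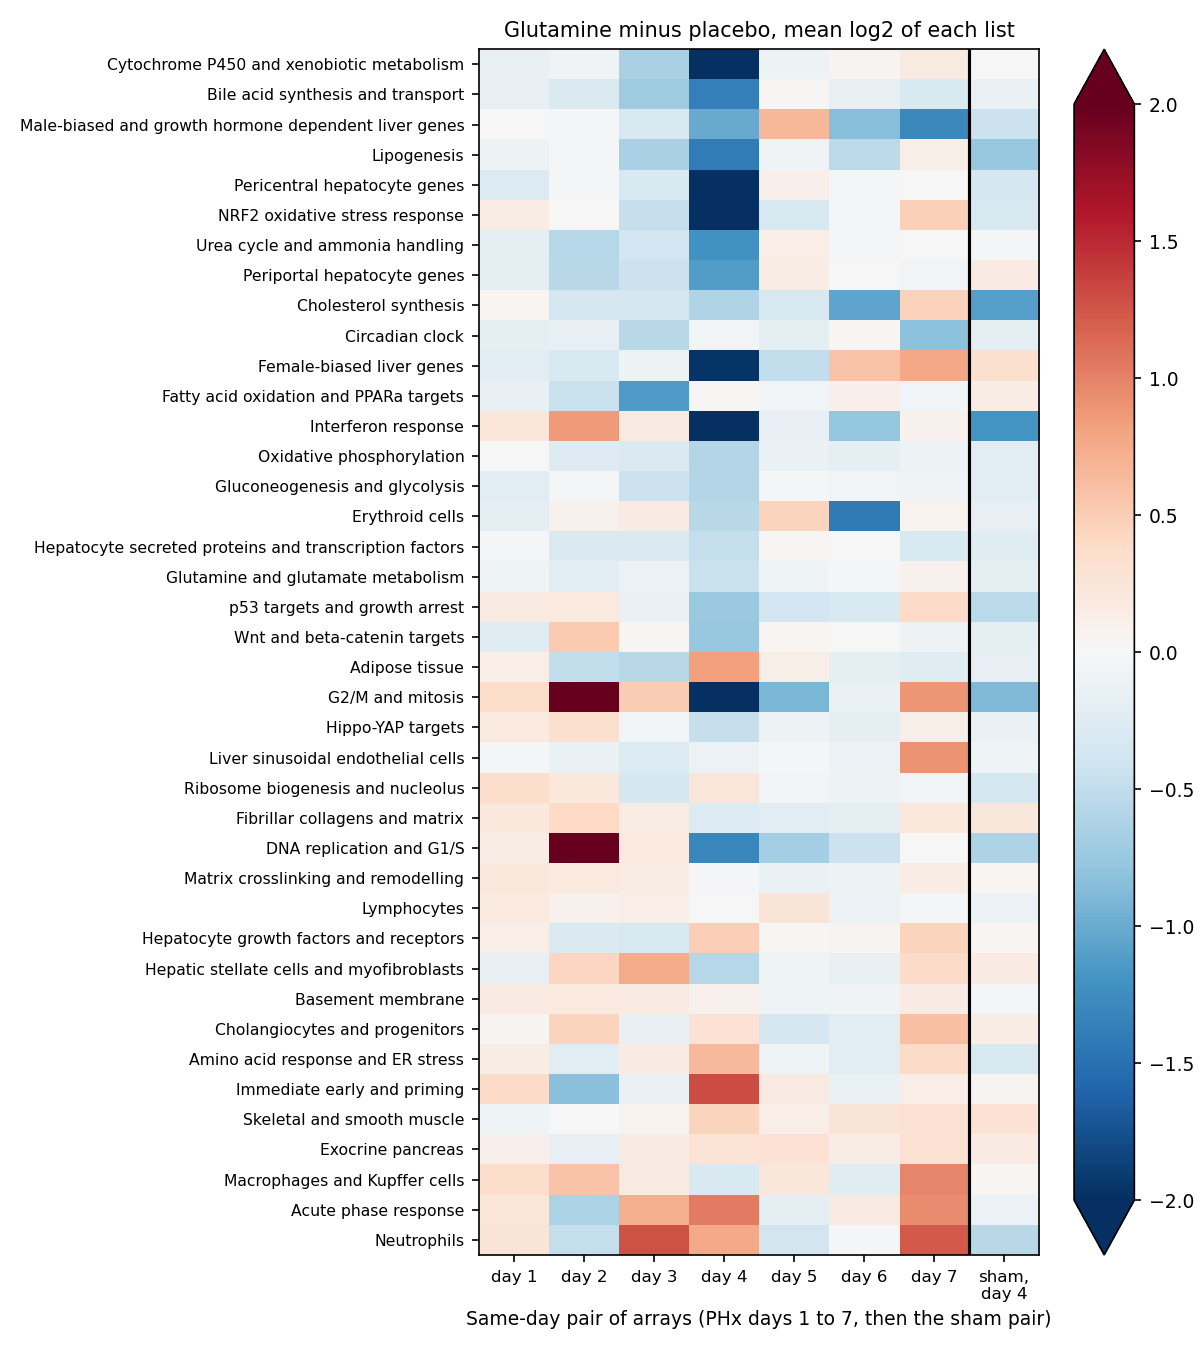
Colour gives, for each of the 40 gene lists (rows), the mean log2 difference between the glutamine and the placebo array of the same day. Columns are days 1 to 7 and the sham pair, with 1 pair of arrays per cell. Oxidative phosphorylation lies below 0 on 7 of 7 days, though on day 1 only at -0.003, and at -0.22 in the sham pair. The P450 list lies at -3.56 on day 4, beyond the end of the colour scale.

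A further question was whether the glutamine difference changed along the days. With limma 0 genes passed for this term, with 601 at an unadjusted p under 0.05 and 0.999 as the smallest adjusted p. The cell cycle lists had differences of opposite sign on days 2 and 4: the mean of DNA replication genes was 2.46 higher with glutamine on day 2 and at -1.30 on day 4, and that of G2/M genes 2.26 higher and at -3.18. Mki67 (gene number 17345, probe on chromosome 7 at 142881591 to 142881650) had a level of -3.64 with placebo and 0.95 with glutamine on day 2, and of 3.11 and -1.77 on day 4. The sham arrays had 1.40 with placebo and 0.16 with glutamine. There was 1 array per drink and day, so these daily values carry no test.

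The last question was whether glutamine acted differently in the sham liver, where there was 1 pair of arrays. In this pair the oxidative phosphorylation mean differed by -0.22, as an untested value, that of cholesterol synthesis by -1.10 and that of the interferon response by -1.19. Me1 differed by -1.21, Lct by 1.06 and Csta3 by -0.09. With limma 1 gene passed for the difference between the sham and the PHx effect: Defa25, of the alpha defensin family, was 5.23 log2 units higher with glutamine in the sham pair and 0.68 higher after PHx, a difference of 4.55 (SE 0.305, adjusted p = 0.00145). A count of 193 genes had an unadjusted p under 0.05. The sham side of this term is 1 pair, and its error comes from the PHx arrays alone. The call was lost without day 1, 2 or 3 (0 genes) and with genes kept only if above the percentile on every array (0 genes), while 3 genes passed without day 4, 15 without the filter and 4 with array weights.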

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

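Both tests of the cell cycle order were chosen after the result was seen. On days 2 and 4 the PHx glutamine and placebo arrays differed in opposite directions in genes of DNA replication and mitosis. The DNA replication list was 2.46 log2 units higher with glutamine on day 2, with the other days between -1.30 and 0.20. The G2/M list was at 2.26 on day 2 and -3.18 on day 4. On day 2 the DNA replication mean, minus that of the sham arrays, was -0.87 with placebo and 1.59 with glutamine. Which series is out of sequence cannot be told from 1 array each. An earlier wave of division with glutamine, past its peak by day 4, was tested with the placebo days as the reference. Across all genes the day 4 glutamine array was nearer to placebo days 1 to 3 than to days 5 to 7 (difference in mean r -0.849), the opposite of the prediction. The test cannot decide the question, since it used all genes and this array also stood apart in lists outside the cell cycle, such as P450 genes. It also decides nothing if a placebo array is itself atypical or misplaced. An exchange of the day 2 and day 4 labels, in either drink, is a candidate explanation. Of the 21 exchanges of 2 glutamine arrays this one gave the lowest variance of the same-day differences, 0.794 times that of the labels as given. The next lowest, 0.890, was that of days 3 and 4, which also moved the day 4 glutamine array. An atypical day 4 array could therefore account for part of the drop. An exchange of the placebo arrays of days 2 and 4 forms the same pairs and so gives the same variance. The value of 0.794 therefore cannot tell which drink's labels would be off. Across genes that are not independent replicates, the day 4 glutamine array had r = 0.648 with placebo day 3 and 0.327 with placebo day 2. The day 2 glutamine array had its highest r, 0.320, with placebo day 4, and 0.241 with placebo day 2, its own labelled day. A response of single mice to glutamine or surgery on these days stays open and untested, with 1 array each.

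On day 4 the differences between the glutamine and the placebo array stood apart from those of the other 6 days in 3 lists. They were pericentral genes at -2.06 (others between -0.31 and 0.10), cytochrome P450 and xenobiotic metabolism genes at -3.56 (others between -0.65 and 0.18), and NRF2 oxidative stress genes at -2.26 (others between -0.46 and 0.47). The list of sinusoidal endothelial cells was at 0.90 on day 7 (others between -0.27 and -0.02), and that of the exocrine pancreas at -0.17 on day 2 (others between 0.10 and 0.30). Of 40 list differences 6 stood apart in this way, 3 of them on day 4, and of all 60 groups of 7 values 9 did. Independent values without any day effect would give about 1 in 20. The lists share members and arrays, and the days are a time course, so these counts do not measure an excess over chance. The day 1 arrays stood apart on the second principal component, at 90.9 with placebo (others between -19.3 and 1.90) and 87.9 with glutamine (others between -44.8 and 4.34). The gene Olfr203 differed by 0.14 on day 6, with the other days between 0.72 and 0.95.

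The glutamine difference of Defa25 was larger in the sham pair than after PHx by 4.55 log2 units, in a tested term. The sham side of this term is 1 pair and its error comes from the PHx arrays alone. It was lost without day 1, 2 or 3 (0 genes) and with genes kept only if above the percentile on every array (0 genes). Among the probes without a gene symbol, which no comparison of the report used, 424 of 6659 (6.40%) passed on day 1 against sham, 232 higher and 192 lower, beside 3708 of 21379 named genes. On day 5, 260 (3.90%) passed, all lower, beside 232 named genes. On day 3 there were 178, on day 2 there were 3 and on day 7 there was 1.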

How the results depend on the processing

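The fits with a covariate for the kind of array file, within each kind, and without the PHx glutamine arrays of day 4 or of days 2 and 4 were chosen after seeing the data. Of 365 values of 19 counts, 255 lay within 1.5 times the reported count and 110 moved further. A count of 0 that stayed at 0 was taken as within. The tallies here include a run on the deposited table of all arrays, which held the same signals and so could hardly differ. Of 2120 list shifts, 1990 kept their side of the threshold and did not count as reversed. A further 80 passed where the reported one did not, 41 no longer passed and 9 reversed. A change of direction counted as reversed only where the reported or the alternative value passed. Values that passed in neither may therefore differ in direction. By the same rule, of 876 values of named genes 711 kept their side of the threshold, 49 newly passed, 116 no longer passed and 0 reversed. The count of 0 genes for glutamine and for its interaction with the day was 0 under every alternative run for it. The cause of the changes was not tested. Background correction from mean signals and a slide block were not run, since the files used here hold no such columns, and signal over background limits the dim genes to an unknown extent.

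With quantile normalization the unadjusted count for glutamine was 1996, the day effect 1769 genes, day 5 against sham 0, and the mean slope of oxidative phosphorylation reversed to 0.0057. Day 3 then had 350 higher and 639 lower genes against 742 and 717, glutamine 3 lists up and 11 down against 0 and 16, and the slope 7 up and 4 down against 5 and 5. With no filter day 2 had 29, day 3 689, day 5 62 and the difference of the glutamine effect between PHx and sham 15 genes. With a filter on every array PHx against sham had 2, day 5 153 and the difference of the glutamine effect 0. The mean of a gene's probes gave 7 genes on day 4, and a trend and robust prior 4 for PHx against sham. Array weights gave 9084 genes for the day effect, 6715 for the slope, 1134 for PHx against sham, 1046, 4490 and 2205 on days 2, 3 and 5, and 4 for the difference of the glutamine effect. A minimum change of 1 log2 unit over days 1 to 7 left 2068 genes with a slope, and the day as a number 734. Without the day as a block the unadjusted count for glutamine was 1308, with 0 genes past the adjusted p and 15 lists against 16. Placebo arrays alone with the day as a number gave 0 genes for the slope, and without the day in the fit 0 for PHx against sham, as did glutamine arrays alone; 2 choices change at once in these 4 fits. With the drink left out PHx against sham had 4 and day 5 had 0. With an estimated correlation 0 lists passed for glutamine, 0 for the slope and 1 for PHx against sham, and with fry 0 for glutamine and 2 for PHx against sham, while 7 passed for the slope.

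Among lists that passed, some no longer did under single settings. With the filter on every array these were, for glutamine, glutamine metabolism (adjusted p = 0.0537) and the interferon response (0.250), and for the slope lymphocytes (0.480) and muscle (0.0836). With the mean of probes they were glutamine metabolism (0.0531) and, for the slope, muscle (0.0941). The interferon response with glutamine also missed with array weights (0.225) and with the covariate for the kind of array file (0.596), and the urea cycle without the PHx glutamine arrays of days 2 and 4 (0.146).

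With a covariate for the kind of array file PHx against sham had 3 genes and day 2 had 10. Within the 6 PHx arrays with one shared lowest signal the unadjusted count for glutamine was 1298, and within the 8 others 648, with 5 lists. Both fits also left out the day, so they do not separate the drink from the day. Without the PHx glutamine array of day 4 the day effect had 7905 genes, the slope 7444, PHx against sham 217, days 1 to 5 had 5792, 1054, 4427, 10 and 516, and the difference of the glutamine effect 3. The glutamine mean of the G2/M list then reversed to 0.49 and that of the interferon response to 0.071. Without the PHx glutamine arrays of days 2 and 4 these counts were 7209, 6656 and 542, then 5803, 823, 4444, 3 and 413 on days 1 to 5, and 0, and the DNA replication mean reversed to -0.15.

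Leaving out each day, and each sham array where it enters, gave these lowest and highest values. The unadjusted glutamine count ran from 2313 to 3718, the day effect from 0 to 8959, the slope from 3 to 7419, and PHx against sham from 0 to 396 genes. Days 1 to 7 ran from 1254 to 5796, 0 to 1054, 0 to 4432, 0 to 2, 0 to 519, 0 to 1 and 0 to 2. The difference of the glutamine effect ran from 0 to 3 genes and the lists for PHx against sham from 10 to 19. Glutamine list means ran from -0.34 to 0.28 for DNA replication (reversed without day 2), -0.41 to 0.49 for G2/M and -0.42 to 0.071 for the interferon response (each reversed without day 4), and -0.11 to 0.084 for sinusoidal endothelial cells (reversed without day 7). Cholesterol synthesis for PHx against sham ran from -0.43 to 0.36 and reversed without the sham placebo array.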

Other observations

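The flips of drink labels for genes past the adjusted p, those with quantile normalization and the day 7 test of Arntl were chosen after the result was seen. On day 3 after PHx, in the list of the amino acid response and stress of the endoplasmic reticulum, 6 of 28 members rose against the 2 sham arrays and 0 fell (13 and 0 adjusted over the list alone), with the secreted stress protein Manf at 2.42 log2 units (SE 0.478), the transcription factor Atf4 at 1.78 (SE 0.355) and the chaperone Hspa5 at 1.93 (SE 0.393). In the list of glutamine and glutamate metabolism 5 of 30 rose and 0 fell (8 and 2 adjusted over the list alone), with the glutamine transporter Slc38a2 at 1.38 (SE 0.236) and the transaminases Got1 at 2.26 (SE 0.465) and Gpt2 at 2.22 (SE 0.558). In the urea cycle list 3 of 12 rose on either adjustment, among them Arg1 at 1.97 (SE 0.332) and Asl at 2.43 (SE 0.481). In the list of male-biased and growth hormone dependent genes 4 of 23 fell (6 lower and 1 higher adjusted over the list alone), with the growth hormone receptor Ghr at -1.22 (SE 0.221) and the transporter Slco1a1 at -6.45 (SE 1.46). Among markers of sinusoidal endothelial cells 3 of 22 fell (5 lower and 3 higher adjusted over the list alone), with the growth factor receptor Kdr at -1.73 (SE 0.298) and the scavenger receptor Stab2 at -1.63 (SE 0.341). The day 3 count over all genes was 1459, but 2 without the sham placebo array and 0 without the sham glutamine array.

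On day 1, in the list of secreted proteins and transcription factors of hepatocytes, 5 of 28 members fell against sham and 1 rose (5 and 2 adjusted over the list alone), with a list median of 0.16. Among those that fell were Foxa2 at -3.52 (SE 0.432), Foxa3 at -2.98 (SE 0.257) and Nr5a2 at -1.68 (SE 0.228). NRF2 targets of the oxidative stress response rose in 3 of 23 cases on either adjustment, with the peroxiredoxin reductase Srxn1 at 2.67 (SE 0.355), Hmox1 at 2.19 (SE 0.490) and Txnrd1 at 1.41 (SE 0.304). Basement membrane genes rose in 4 of 14 cases on either adjustment, with Col4a1 at 1.97 (SE 0.374) and the laminin chain Lamc1 at 1.29 (SE 0.189). In the list of glutamine and glutamate metabolism 3 of 30 rose and 2 fell on either adjustment, with Slc38a2 at 3.36 (SE 0.236), Got1 at 2.47 (SE 0.465) and Aldh18a1, of proline synthesis, at -1.33 (SE 0.308). The day 1 count over all genes was 3708, with 1397 without the sham placebo array and 1254 without the sham glutamine array.

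With glutamine, dim genes had higher values and the bright lists of liver metabolism lower ones, by camera with its preset correlation in 16 lists, of which 0 passed with an estimated correlation (smallest adjusted p 0.448) or with fry (0.312). The kind of array file is argued against as the whole cause: on days 2, 3 and 5, when both arrays were of one kind, the brightest minus the dimmest 10% of genes still differed by a mean of -0.374. A difference by brightness alone cannot be told apart from other causes: 12 of the 16 lists had a median under the 2.5th percentile of 10000 random lists of the same size and brightness, but 21 of all 40 lists lay outside the limits on either side where 2 were due, so random genes spread less than real lists. The 4 that did not lie under it were fatty acid oxidation (at 2.71%), oxidative phosphorylation (3.19%), gluconeogenesis (18.0%) and hepatocyte secreted proteins (27.4%). The drink remains a candidate explanation, as the brightness difference lay above 0 on 0 of 7 days, between -0.052 and -0.874, and was -0.611 in the sham pair. Handling of the arrays by drink stays open, since their slides are not given in the sources used here. Mouse numbers also split by drink without overlap, in the sham pair too, so the order or cohort of the mice cannot be told apart from the drink.

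Drink labels were flipped within days in all 64 ways, the real labels included. For genes at an unadjusted p under 0.05, 1 of 64 gave as many as the real 3577, with 3280 as the highest other. With quantile normalization 3 of 64 gave as many as the real 1996, and the highest other was 2161, above the real count. The real count was thus reached by under 5% of the flips with either normalization, but narrowly so with quantile normalization. Chance is not firmly excluded for this count, as the flip tests were not adjusted for their number. Nor could chance be excluded for the lists (33 of 64, real 16, highest other 22) or for the interaction with the day at an unadjusted p under 0.05 (12 of 64, real 601, highest other 893). For genes past the adjusted p the flips decide nothing, since the real count was 0 and 64 of 64 must give at least that, with 0 as the highest other.

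The clock genes Arntl, an activator, and Dbp, an output gene of the opposite phase, set 5 arrays apart with low Arntl and high Dbp: both sham arrays, placebo days 6 and 7 and glutamine day 6. Surgery and the day after it cannot be told apart from other causes: the day 7 difference in Arntl between the drinks, 2.59 log2 units, lay 4.08 SD from the mean of the other days, but rests on 1 pair of arrays. Nor can killing at different times of the clock day: over the 14 PHx arrays the means of the other members of each phase had r = -0.243 (permutation p = 0.404) and Spearman's rho -0.248 (permutation p = 0.391), and r = 0.084 without the 2 arrays farthest from the median. The time of killing is not given in the sources used here. The day 5 comparison with sham, where the clock repressors Ciart and Per3 fell, used these sham arrays.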
